A study of Danio rerio with 2 samples.

How the data were processed

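The series holds 1 droplet library (10x Genomics 3' chemistry, version 3.1 per the labels) from cells of DMSO control larvae and 1 from cells of PFOS-exposed larvae, each from whole bodies at 72 hours after fertilisation. The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.1 per the file headers on the GRCz11 genome build per the labels. Barcodes had already been called as cells, and no barcode held under 500 UMIs. The annotation release and the treatment of intronic reads are not stated. The DMSO library had 6434 barcodes and 30264791 UMIs, and the PFOS library 8178 barcodes and 35905646 UMIs, over 32520 genes.

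All values below were computed from those counts. Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 6055 DMSO and 7842 PFOS cells. Doublet scores were computed per library by a reimplementation of the Scrublet approach, which compares each cell with simulated sums of 2 cells. The highest scores were removed, as many as 0.8% per 1000 cells of the library (293 DMSO and 492 PFOS cells). The kept cells, 5762 and 7350, held 26312956 and 30422207 UMIs. Free RNA was not estimated from empty droplets, which were not analysed here.

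Cells of both libraries were clustered together on log counts per 10000 with 3000 variable genes chosen within each library, 40 principal components, 20 neighbours and the Leiden method at resolution 1.5, without batch correction. This gave 36 clusters, of which 28 were named from 43 marker sets fixed before the data were examined. A name needed at least 3 markers, and at least 20% of the set, at 4-fold over the other cells and in at least 10% of the cells. No other set could hold more of the cluster's 10 leading genes, and shallow clusters needed a marker among those. These limits were set after the clusters were seen. So was a limit that left a cluster unnamed when another set supplied at least 3 of its 10 leading genes. Clusters with the same name were merged, and names carry "-like" because markers alone support them. A list of genes marking dividing cells was read as a state and gave no name.

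Class shares are percentages of the kept cells with exact Clopper-Pearson 95% intervals. For the whole library and for each class with at least 100 cells in both libraries, UMIs were summed and scaled to the total of that library or class as CPM. Ratios of PFOS to DMSO have exact conditional binomial 95% intervals. Genes needed at least 100 UMIs over both libraries, or at least 50 within a class. A count of 0 was set to a floor of 3 counts, summed over the library, and such folds are lower bounds. All intervals cover counting error only, because cells of 1 library are not replicates. No test between treatments, p-value or standard error was computed, and counts of genes or classes past a fold are counts by size. Values shared across classes are medians of the log2 ratios over at least 5 classes.

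For 36 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on expression in 20 bins. A list needed at least 5 measured members. Its percentile describes these libraries and is not a test of the treatment.

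Genes named in the text follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes of the whole library by the interval bound nearest to no difference, and in each class the 5 highest and 5 lowest by that bound. Within classes it leaves out genes over 10 times more abundant in another class. It adds the 8 highest and 8 lowest medians across classes, up to 4 abundant members of each list, and the genes ins, gcga, sst1.1 and sst2. Loci with clone-like names were counted and not named, and only part of the genes the rule selects is named here. Of the genes with values in the text, 62 follow another rule, chosen after the values were seen. It asks for at least 20 cells with the gene, no cell with over 20% of its UMIs, and a fold of at least 1.5 with doublets kept, after thinning and at equal cluster shares, wherever these could be measured. It ranks by the interval bound without the richest cell and takes up to 8 genes per side. Agreement of those genes across these settings is therefore built in. The comparison of classes of at least 10 cells with doublets kept and the limits for hormone-rich and enzyme-rich cells were also chosen after the values were seen.

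Alternatives chosen before the data were examined were a mitochondrial limit of 10%, at least 1000 UMIs and 500 genes per cell, no removal of doublets, and resolutions of 0.8 and 3. Others were scaling each gene within its library before clustering, scaling by the median gene ratio, totals without mitochondrial and ribosomal protein genes, and gene filters of 0.5 and 2 times the minimum. Cells were also thinned to 1000 UMIs each, which kept 3991 DMSO and 5065 PFOS cells, class shares were set equal in both libraries, and random lists were matched in 10 bins. Alternatives chosen after seeing the data were leaving out the cell richest in a gene, setting equal shares for the clusters of a class with at least 15 cells in each library, and naming clusters without the added limit.

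The procedure was tested on simulated counts with 200 genes changed by known folds in the whole library, in neurons and in photoreceptors. The intervals covered the true ratio for 95.3%, 96.02% and 95.7% of genes. The simulated counts were drawn from the pooled profile with counting error only, so spread between cells was left out. Coverage near 95% is therefore built in and says nothing of genes carried by few cells. All measured changed genes had the right direction. Of the unchanged genes, 0, 43 and 12 were at least 2-fold apart, and 1 list in each set lay outside the central 95% of random lists. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.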

Results

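Perfluorooctane sulfonate (PFOS) is a persistent surfactant. Cells of whole zebrafish larvae carrying a reporter of insulin-producing cells were captured at 72 hours after fertilisation. Exposure to 16 µM PFOS, or to 0.01% DMSO as control, had begun at 3 hours. After filtering, 5762 DMSO cells and 7350 PFOS cells remained, with medians of 1823 and 1630 UMIs per cell. Each treatment has 1 library, so no test between treatments exists, and the exposure cannot be separated from the clutch, the dissociation or the capture. Intervals are 95% and cover counting error only. For a gene, the parentheses give its CPM with PFOS, its CPM with DMSO, and the fold with its interval. For a gene list, they give the median log2 ratio, how many measured genes shared its direction and, for a list outside the random range, the planned settings that brought it inside. Settings that gave a list no value are not marked, so a list without such a note was not always measured in all 12. Intestinal apolipoproteins and progenitor myelin genes had values in 10, and erythroid glycolysis genes in 9. Values were also computed with the cells scored as doublets kept and after thinning each cell to 1000 UMIs. With doublets kept, cells were clustered and named anew. A change of a class value there can come from the doublets or from the new classes. Gene values were also computed without the cell richest in the gene and at equal class or cluster shares. Where such a setting moved a value by more than 1.5 times or turned its direction, that value follows. Gene list medians over all cells were not computed at equal class shares, so how far cell composition carried them was not tested. No list median was computed without the richest cell.

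With PFOS the library held more nervous system cells and fewer red blood, gut and liver cells. Of 19 classes, 4 had shares at least 1.5-fold higher and 4 at least 1.5-fold lower, as counts by size. With a mitochondrial limit of 10%, 2 classes were at least 1.5-fold higher. Neuron-like cells took 11.6% (10.9 to 12.4) of PFOS cells and 4.67% (4.14 to 5.25) of DMSO cells. Bipolar, amacrine or other retinal neuron-like cells took 4.83% (4.35 to 5.35) of PFOS cells and 2.204% (1.84 to 2.62) of DMSO cells. Neural progenitor-like cells took 7.12% (6.54 to 7.73) of PFOS cells and 4.67% (4.14 to 5.25) of DMSO cells. Skeletal muscle-like cells took 1.66% (1.38 to 1.98) of PFOS cells and 0.816% (0.5999 to 1.08) of DMSO cells. If a further cluster that mixed lens crystallin and muscle transcripts was named muscle as well, which a limit set after the clusters were seen prevented, their share was 0.951 times the DMSO share. Erythroid-like cells took 2.16% (1.84 to 2.52) of PFOS cells and 5.36% (4.80 to 5.98) of DMSO cells. Intestinal epithelium-like cells took 1.80% (1.505 to 2.13) of PFOS cells and 3.002% (2.58 to 3.48) of DMSO cells. Hepatocyte-like cells took 0.381% (0.253 to 0.550) of PFOS cells and 0.833% (0.615 to 1.103) of DMSO cells. Olfactory sensory neuron-like cells took 0.612% (0.447 to 0.818) of PFOS cells and 1.09% (0.841 to 1.397) of DMSO cells. Photoreceptor-like cells differed little, at 5.33% (4.83 to 5.87) of PFOS cells and 4.91% (4.37 to 5.50) of DMSO cells. So did smooth muscle-like cells, at 1.28% (1.03 to 1.56) of PFOS cells and 1.27% (0.994 to 1.59) of DMSO cells. Macrophage-like, fibroblast-like and pronephros-like shares were 0.906, 0.887 and 0.7999 times the DMSO share. The corresponding ratios were 0.789 for superficial epidermis-like, 0.701 for basal epidermis-like, 0.771 for fin fold mesenchyme-like, 0.733 for cartilage-like, 0.764 for endothelial-like and 0.738 for ionocyte-like cells.

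**Figure D1:**
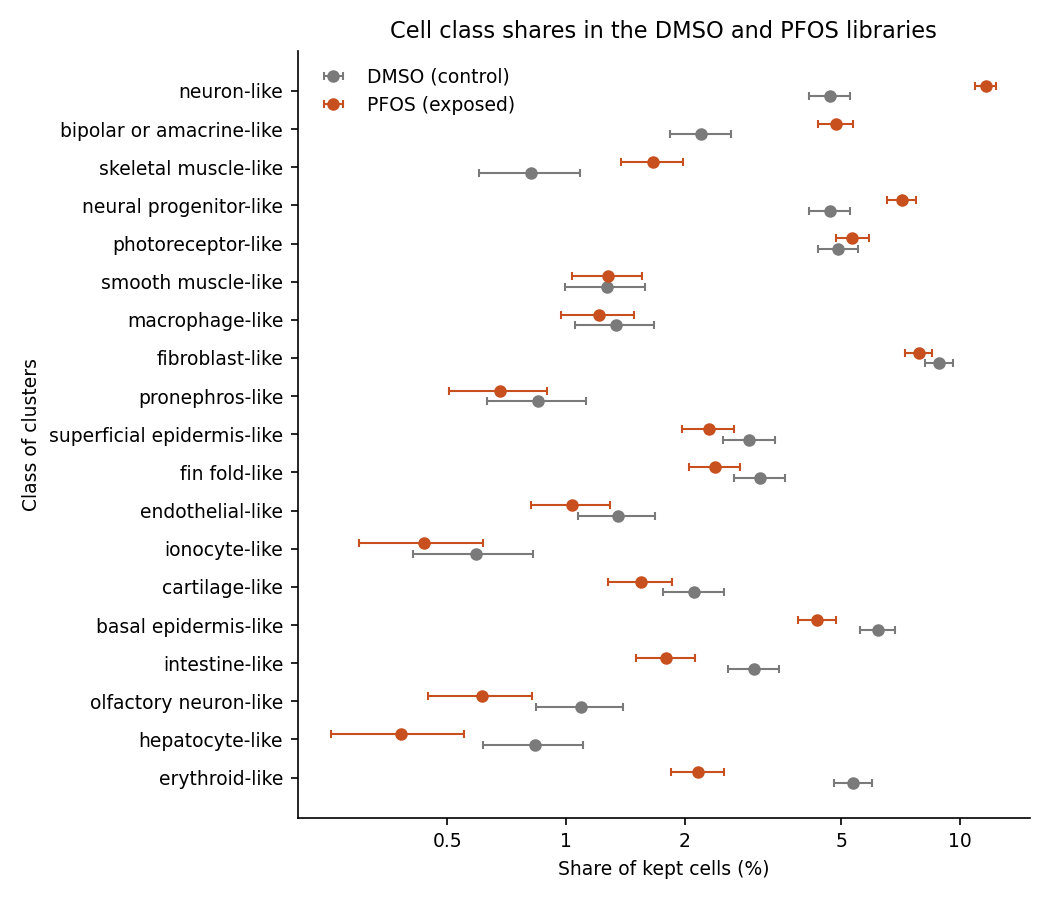
Share of kept cells in each marker-named class for the DMSO and PFOS libraries, on a log scale, with exact 95% binomial intervals that cover counting error only. Classes are ordered by the ratio of the PFOS share to the DMSO share.

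Neuron-like cells came from 3 clusters, and each was larger with PFOS. Cluster 3 held 205 DMSO and 655 PFOS cells, cluster 21 held 33 and 139, and cluster 31 held 31 and 60. Over 6 other settings of filters and clustering the neuron ratio stayed between 1.67 and 2.83, and the erythroid ratio between 0.388 and 0.444. The muscle ratio was less stable, from 1.24 to 4.603, and the hepatocyte ratio reached 0.738. Most DMSO erythroid-like cells lay in cluster 20 (172 DMSO and 54 PFOS cells), whereas most PFOS ones lay in cluster 18 (137 DMSO and 105 PFOS cells). Genes leading a cluster differed at least 1.5-fold within their own class for 7 of 20 erythroid, 4 of 10 intestinal, 8 of 20 progenitor, 9 of 20 photoreceptor and 4 of 30 neuron leading genes. The counts were 11 of 20 for fin fold mesenchyme, 6 of 10 for cartilage, 7 of 20 for bipolar or amacrine cells and 4 of 20 for superficial epidermis. They were 2 of 10 for basal epidermis and 1 of 20 for fibroblasts. Cluster shares and expression ratios within clusters are therefore not independent. Clusters without a name held 43.9% of DMSO and 41.4% of PFOS cells. Among them, the cluster of mixed lens and muscle transcripts held 4.55% and 3.44%.

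Removing high doublet scores took out 83.1% of lens-like, 80% of hatching gland-like and 61.1% of exocrine pancreas-like cells, so these classes fell out of the comparison. These percentages and those below refer to classes clustered and named anew with doublets kept, which held other cells than the classes above. There neuron-like cells numbered 720 with DMSO and 1556 with PFOS, against 269 and 854 above. Photoreceptor-like cells numbered 175 and 246, against 283 and 392 above. Removal was uneven in other classes. It took 16.7% of PFOS but 3.43% of DMSO photoreceptor-like cells, and 12.2% of PFOS but 1.28% of DMSO erythroid-like cells. The corresponding values were 45.6% and 21.8% for hepatocyte-like and 31.8% and 8.82% for olfactory sensory neuron-like cells. It took 58 of 214 PFOS and 35 of 91 DMSO skeletal muscle-like cells.

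Endocrine transcripts differed through a few cells. Cells with at least 20 UMIs and at least 1% of their UMIs from the somatostatin genes sst2 and sst1.2 numbered 0 with DMSO and 8 with PFOS. Insulin-rich cells numbered 2 and 4, glucagon-rich cells 2 and 0, growth hormone-rich cells 0 and 2, and thyrotropin-rich cells 2 and 0. These limits were set after the values were seen. Summed over the library, sst2 (769.5 and 3.19 CPM, 241-fold, 195 to 302, thinned 58.3) and sst1.2 (735 and 3.42 CPM, 215-fold, 175 to 267, thinned 40.7) were far higher with PFOS. The insulin transcript ins (272 and 55.1 CPM, 4.94-fold, 4.67 to 5.23, thinned 1.63, without richest cell 2.87) was also higher. It had 1450 UMIs in DMSO and 8286 in PFOS, of which 1 PFOS cell held 5816. The other fixed hormone genes were sst1.1, higher (14.7 and 5.74 CPM, 2.56-fold, 2.12 to 3.10, thinned 1.07, without richest cell 0.925), and gcga, lower (10.1 and 26.8 CPM, 2.65-fold, 2.31 to 3.04, thinned 4.02). Of the pituitary hormones, gh1 (89.0 and 3.002 CPM, 29.6-fold, 23.7 to 37.6, without richest cell 12.1) and prl (21.4 and 2.204 CPM, 9.72-fold, 7.43 to 12.9, thinned 2.61, without richest cell 1.51) were higher. The thyrotropin gene tshba (1.51 and 32.9 CPM, 21.8-fold, 16.2 to 29.96, thinned 13.5, without richest cell 12.9) was lower. Cells with at least 5% of their UMIs from pancreatic digestive enzymes numbered 9 with DMSO and 1 with PFOS before doublet removal, which took all of them. That PFOS cell held 26 of 19845 enzyme UMIs in all PFOS cells, while the PFOS cell richest in them held 2175. By markers, exocrine pancreas-like cells numbered 16 with DMSO and 20 with PFOS before removal. Their median depth was 9390 UMIs with DMSO and 38137 with PFOS, so the limit by percentage does not count such cells.

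Over all cells, transcripts of the developing brain, synapses and muscle were higher with PFOS. Transcripts of photoreceptors, gut absorption, plasma lipoproteins and the extracellular matrix were lower. Of 17927 genes with at least 100 UMIs, 361 were at least 2-fold higher and 288 at least 2-fold lower, counted by size. The higher ones made up 55.6% of these, and 44.3% when libraries were scaled by the median gene ratio. Cell composition carried much of the higher side: at equal class shares, 92 of the higher and 210 of the lower genes were still 2-fold apart.

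Among the fixed gene lists, neural progenitor genes (median 0.76, 25 of 25 higher), synaptic genes (median 0.60, 33 of 37 higher), sarcomere genes (median 0.89, 34 of 37 higher) and muscle energy genes (median 0.54, 17 of 21 higher) lay above the central 95% of matched random lists. So did cell cycle genes (median 0.42, 26 of 32 higher) and pancreatic and gut hormones (median 0.55, 16 of 23 higher). The other 18 lists outside the random range lay below it. They were led by intestinal absorption (median -1.101, 16 of 17 lower) and phototransduction (median -1.07, 25 of 26 lower). Next came digestive enzymes (median -0.86, 10 of 12 lower, doublets kept -2.67), apolipoproteins (median -0.74, 14 of 17 lower) and crystallins (median -0.55, 25 of 27 lower, doublets kept -1.99). Ion transport of skin and kidney (median -0.43, 18 of 24 lower, thinned 0.06, inside the random range: 10% mitochondrial limit, doublets kept, thinned), collagens and extracellular matrix (median -0.33, 29 of 37 lower) and complement and acute phase proteins (median -0.31, 27 of 34 lower) followed. Glycolysis (median -0.28, 26 of 29 lower) and xenobiotic metabolism (median -0.28, 20 of 26 lower, inside the random range: thinned) were similar. Smaller shifts appeared in hemoglobins and heme synthesis (median -0.28, 16 of 22 lower, thinned -0.92), myelin (median -0.22, 7 of 11 lower, inside the random range: doublets kept, thinned, halved gene filter) and cholesterol synthesis (median -0.20, 19 of 23 lower, inside the random range: thinned). Nuclear oxidative phosphorylation (median -0.19, 50 of 50 lower), keratins (median -0.18, 29 of 37 lower) and the thyroid and nuclear receptor axis (median -0.18, 8 of 13 lower) were of that size too. Fatty acid oxidation and PPAR targets (median -0.16, 34 of 44 lower) and Nrf2 targets (median -0.09, 22 of 35 lower, inside the random range: 1000 UMIs) shifted least.

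The remaining lists stayed inside the random range. Their medians were 0.00 for fatty acid synthesis, -0.19 for bile acid synthesis, 0.10 for heat shock and the unfolded protein response, 0.03 for immediate early genes and 0.04 for p53 targets. Inflammation had 0.12, iron handling -0.09, cardiac contraction 0.00, estrogen response -0.20, hypoxia 0.04, ribosomal proteins 0.05 and mitochondrially encoded genes -0.09.

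**Figure D2:**
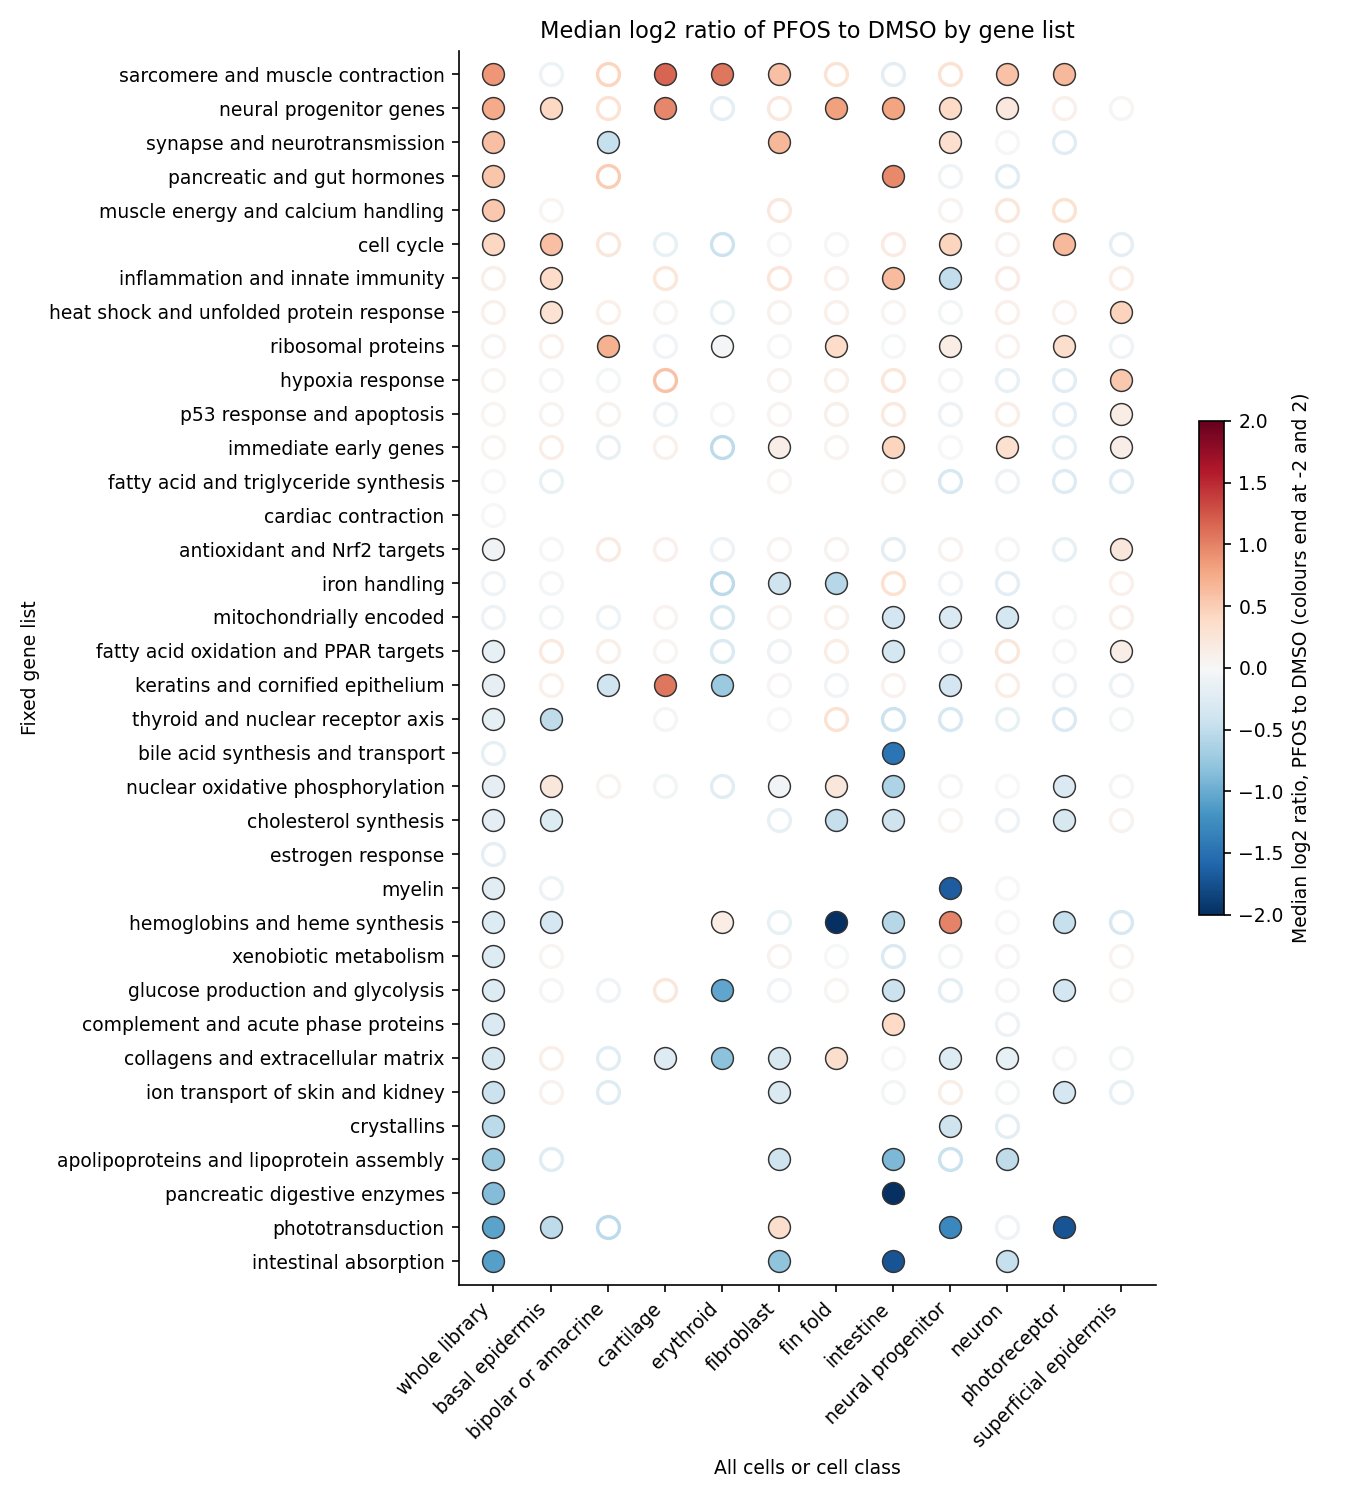
Median log2 ratio of PFOS to DMSO for each fixed gene list over all cells and within each class with at least 100 cells per library. Filled circles lie outside the central 95% of expression-matched random lists, open circles inside it. Lists with under 5 measured genes are left blank.

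The transcription factor genes atoh7 (11.7 and 1.56 CPM, 7.51-fold, 5.43 to 10.6, thinned 4.49), otpb (5.98 and 0.798 CPM, 7.50-fold, 4.76 to 12.4, equal classes 4.66) and vsx1 (95.3 and 20.4 CPM, 4.66-fold, 4.25 to 5.12, equal classes 2.35) were higher over all cells. So were gsx1 (6.74 and 1.14 CPM, 5.91-fold, 4.02 to 8.98, without richest cell 10.8, equal classes 3.27) and bhlhe23 (10.9 and 1.79 CPM, 6.11-fold, 4.49 to 8.48, doublets kept 3.54, equal classes 3.37). The radial glial genes her15.1 (384 and 178 CPM, 2.16-fold, 2.09 to 2.24) and fabp7a (528 and 408 CPM, 1.29-fold, 1.26 to 1.32, equal classes 0.943) were higher. The synaptic gene syt1a (151 and 106 CPM, 1.42-fold, 1.35 to 1.49, equal classes 0.920) went the same way. At equal class shares fabp7a and syt1a no longer did. The neuropeptide genes pmchl (5.79 and 0.0760 CPM, 76.1-fold, 20.8 to 633, thinned 25.2, without richest cell 13.8) and nmba (16.9 and 1.48 CPM, 11.4-fold, 8.23 to 16.2, thinned 2.81) rested on few cells. So did pdyn (4.47 and 0.228 CPM, 19.6-fold, 8.78 to 54.4), nppal (6.18 and 0.304 CPM, 20.3-fold, 10.1 to 47.8) and cnfn (23.96 and 3.95 CPM, 6.06-fold, 4.93 to 7.52, thinned 1.34). Fast muscle genes mylpfa (210.2 and 81.0 CPM, 2.60-fold, 2.47 to 2.73) and myhz1.3 (28.96 and 5.55 CPM, 5.22-fold, 4.38 to 6.26) and the titin genes ttn.1 (74.6 and 40.4 CPM, 1.85-fold, 1.72 to 1.99, equal classes 1.204) and ttn.2 (97.46 and 55.8 CPM, 1.75-fold, 1.64 to 1.86, equal classes 1.13) were higher.

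Cone genes were lower over all cells, among them the opsins opn1lw2 (139.7 and 477 CPM, 3.41-fold, 3.30 to 3.54, doublets kept 1.43) and opn1sw1 (124 and 338 CPM, 2.73-fold, 2.62 to 2.83). The phototransduction genes gngt2b (298 and 881 CPM, 2.95-fold, 2.88 to 3.02, doublets kept 1.77) and arr3a (119 and 231 CPM, 1.94-fold, 1.86 to 2.02, doublets kept 1.24) were lower as well. Gut transcripts followed with rbp2a (19.5 and 83.4 CPM, 4.28-fold, 3.91 to 4.69, doublets kept 2.82, thinned 2.59), fabp2 (71.7 and 179 CPM, 2.499-fold, 2.37 to 2.63) and fabp1b.1 (60.1 and 136 CPM, 2.27-fold, 2.14 to 2.4001, thinned 1.29). Liver transcripts followed with apoa1b (88.8 and 182 CPM, 2.05-fold, 1.95 to 2.15), apoa2 (73.1 and 137 CPM, 1.88-fold, 1.78 to 1.98) and tfa (68.4 and 139 CPM, 2.03-fold, 1.93 to 2.15). Cartilage collagen col2a1a (733 and 1243 CPM, 1.69-fold, 1.67 to 1.72), the enolase eno3 (127 and 289.7 CPM, 2.28-fold, 2.197 to 2.38) and the thyroid hormone receptor gene thrab (235 and 364 CPM, 1.55-fold, 1.501 to 1.596) were lower too. The adult globin genes hbba1 (0 and 14.2 CPM, at least 144-fold, doublets kept 447, thinned 21.2) and hbaa1 (0.0986 and 12.5 CPM, 127-fold, 43.01 to 618, thinned 26.2, equal classes 64.3) were lower through 1 DMSO cell each. It held 373 of 374 DMSO UMIs of hbba1 and 328 of 329 of hbaa1. The remaining DMSO cells had 1 UMI of each gene, against 0 and 3 with PFOS. The embryonic globin hbbe1.3 (13620.0 and 17869 CPM, 1.31-fold, 1.31 to 1.32, equal classes 0.589) was lower over all cells but higher at equal class shares. Other lower genes were glulc (0.362 and 17.3 CPM, 47.9-fold, 26.5 to 96.7, thinned 24.1, without richest cell 16.6), matn3b (0.493 and 8.97 CPM, 18.2-fold, 10.8 to 33.0, thinned 9.31, without richest cell 2.13) and rhcgb (1.74 and 15.5 CPM, 8.88-fold, 6.66 to 12.1, thinned 3.97). The gene ccl38a.4 was lower (0.0986 and 4.07 CPM, 41.2-fold, 13.7 to 203), but 1 DMSO cell held 106 of its 107 DMSO UMIs, which left 1 against 3 with PFOS. Lower genes also included adcyap1a (0.394 and 5.28 CPM, 13.4-fold, 7.43 to 26.5, without richest cell 6.31) and the odorant receptors or111-4 (0.0657 and 8.17 CPM, 124-fold, 33.99 to 1033, doublets kept 64.3) and or109-11 (0.132 and 7.45 CPM, 56.7-fold, 21.8 to 210.0). Of the 24 genes with the most extreme whole-library folds, 15 had over 50% of their UMIs in 1 cell of the higher library, and 21 were still 1.5-fold apart without it. The other 3 were left with at most 4 UMIs each: hbaa1 and ccl38a.4 then had more with PFOS, and hbba1 had 1 UMI with DMSO and none with PFOS.

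Within classes, 11 of which had at least 100 cells in each library, 1997 gene and class pairs were at least 2-fold higher with PFOS and 1909 at least 2-fold lower. The higher and lower pairs numbered 239 and 313 after thinning and 745 and 850 with the doubled gene filter. With the halved filter they numbered 4899 and 4104. Single cells often decided the extremes: among the 110 most extreme pairs, 51 had over 50% of their UMIs in 1 cell, and 78 were still 1.5-fold apart both without that cell and with doublets kept. Without it, 6 pairs no longer kept their direction, some only through the floor set for counts of 0. With doublets kept, 8 of the 100 pairs that could still be measured changed direction. Genes named below were therefore drawn mainly from those spread over at least 20 cells, a choice made after their values were seen. Gene lists lay above the central 95% of random lists in 42 pairs of list and class and below it in 46. After thinning, which leaves fewer genes to measure, these pairs numbered 10 and 9.

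Summed over the class, intestinal epithelium-like cells with PFOS had lower transcripts for absorbing and packaging nutrients. The median depth of the class was 4933 UMIs with PFOS and 2688 with DMSO. The class was 1 cluster, so equal cluster shares could not be set. Whether the mix of cells within it differed was not tested. Every measured intestinal absorption gene was lower (median -1.72, 13 of 13 lower, thinned -0.77), as was every apolipoprotein (median -0.91, 9 of 9 lower). Oxidative phosphorylation genes (median -0.62, 48 of 49 lower) and mitochondrially encoded genes (median -0.37, 13 of 13 lower, inside the random range: thinned) were also lower. So were fatty acid oxidation genes (median -0.36, 28 of 32 lower, thinned 0.30, inside the random range: thinned) and bile acid genes (median -1.46, 4 of 5 lower). Pancreatic enzyme genes, which mark another cell type, were lower in the class as well (median -3.22, 8 of 9 lower). Among them prss59.2 had 819 DMSO UMIs and 1 with PFOS, and 1 DMSO cell held 89.99% of the former. Immediate early genes (median 0.44, 27 of 28 higher) and inflammatory genes (median 0.63, 9 of 12 higher, inside the random range: 1000 UMIs, halved gene filter) were higher. The retinoid-binding gene rbp2a (142.7 and 771 CPM, 5.40-fold, 4.67 to 6.27, thinned 3.47) and the apolipoprotein gene apoa1b (403 and 626 CPM, 1.55-fold, 1.41 to 1.72) were lower. The fatty acid binding genes fabp2 (891 and 1814 CPM, 2.04-fold, 1.91 to 2.17), fabp1b.1 (569 and 1313 CPM, 2.31-fold, 2.13 to 2.499, thinned 1.34) and fabp6 (5.41 and 98.4 CPM, 18.2-fold, 9.04 to 42.7) were lower too. Steroid-modifying genes sult2st2 (96.7 and 361 CPM, 3.73-fold, 3.11 to 4.50) and srd5a2a (13.5 and 85.9 CPM, 6.35-fold, 3.98 to 10.7) and transport genes aqp8a.2 (39.9 and 155 CPM, 3.87-fold, 2.92 to 5.21) and slc7a7 (6.76 and 33.3 CPM, 4.93-fold, 2.51 to 10.8, without richest cell 8.16) were lower as well. Higher genes included agr2 (1365 and 219.7 CPM, 6.21-fold, 5.59 to 6.92, thinned 2.97) and sox4b (43.3 and 8.33 CPM, 5.197-fold, 2.97 to 9.63). The same held for id1 (325 and 117 CPM, 2.79-fold, 2.38 to 3.28) and lgals3b (127 and 36.96 CPM, 3.44-fold, 2.61 to 4.59).

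Photoreceptor-like cells with PFOS carried less of the phototransduction machinery. All measured phototransduction genes were lower (median -1.72, 24 of 24 lower), including opn1lw2 (1852 and 9009.6 CPM, 4.86-fold, 4.67 to 5.07, doublets kept 1.72), opn1sw1 (1636 and 5436 CPM, 3.32-fold, 3.17 to 3.48) and gngt2b (4805 and 16782 CPM, 3.49-fold, 3.40 to 3.59, doublets kept 2.096). Outer segment genes rcvrn3 (66.6 and 892 CPM, 13.4-fold, 10.9 to 16.6, doublets kept 3.07), prph2b (35.3 and 365 CPM, 10.4-fold, 7.78 to 14.03, doublets kept 3.70, thinned 5.38) and guca1c (24.7 and 185 CPM, 7.49-fold, 5.28 to 10.9, doublets kept 4.09, thinned 4.46) had larger folds. So did the synaptic gene cplx4a (90.6 and 655 CPM, 7.23-fold, 6.03 to 8.73, doublets kept 3.10). Oxidative phosphorylation (median -0.29, 45 of 47 lower, inside the random range: thinned) and glycolysis genes (median -0.36, 14 of 17 lower, inside the random range: thinned) were lower, and ribosomal protein genes higher (median 0.35, 72 of 72 higher). Higher genes included marcksl1b (422 and 148 CPM, 2.84-fold, 2.41 to 3.36), hmgn2 (1065 and 458 CPM, 2.33-fold, 2.11 to 2.56) and the neuronal transport gene kif1aa (32.6 and 5.53 CPM, 5.91-fold, 2.66 to 15.5). Transcripts of other cell types differed here too. The log2 ratio was 0.75 for mylpfa, 1.42 for lyz, -2.74 for prss59.2 and -1.05 for krt92. The hemoglobin list and the sarcomere list (inside the random range: 10% mitochondrial limit, doublets kept) also lay outside the random range.

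In the bipolar or amacrine-like class ribosomal protein genes were higher (median 0.71, 72 of 72 higher) and synaptic genes lower (median -0.46, 20 of 21 lower). The keratin list, which marks epithelia such as skin and gut, also lay outside the random range in this class (inside it: 10% mitochondrial limit). Here prkcaa (65.7 and 239.7 CPM, 3.65-fold, 2.58 to 5.18) and nlgn1 (421 and 1051 CPM, 2.49-fold, 2.15 to 2.89) were lower. The regulators sall1a (123 and 22.98 CPM, 5.36-fold, 2.53 to 13.6), bhlhe23 (223 and 55.8 CPM, 3.9998-fold, 2.44 to 6.99) and tfap2c (289 and 95.2 CPM, 3.03-fold, 2.07 to 4.61) were higher. Median ratio scaling moved all genes of this class by 0.17 log2 and the higher share of its 2-fold genes from 43.8% to 71.4%. With doublets kept the class held 98 DMSO cells, and after thinning 88, below the minimum of 100, so its genes were not compared in those settings.

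Neural progenitor-like cells differed in several gene lists. Cell cycle genes (median 0.45, 25 of 31 higher) and neural progenitor genes (median 0.40, 20 of 23 higher) were higher. Examples were dbx1b (63.2 and 8.91 CPM, 7.09-fold, 3.96 to 13.98), her2 (1171 and 471 CPM, 2.49-fold, 2.28 to 2.71) and six3a (27.99 and 6.68 CPM, 4.19-fold, 2.097 to 9.50, doublets kept 7.85). The cyclin gene ccnb1 (76.4 and 39.4 CPM, 1.94-fold, 1.43 to 2.68, doublets kept 3.79, without richest cell 3.62) and abhd6a (2252 and 851 CPM, 2.65-fold, 2.48 to 2.82) were higher too. Myelin genes, many of which were markers of oligodendrocytes or Schwann cells, were lower (median -1.66, 8 of 8 lower). No class of those cells was named, and their transcripts were not separated from those of this class. Mitochondrially encoded genes were also lower (median -0.29, 13 of 13 lower, inside the random range: 10% mitochondrial limit). The genes mcamb (13.99 and 72.8 CPM, 5.1997-fold, 3.55 to 7.74, thinned 2.67) and ptgdsb.2 (14.7 and 50.5 CPM, 3.43-fold, 2.30 to 5.19) were lower too. So were scn4ab (20.5 and 90.6 CPM, 4.43-fold, 3.21 to 6.18) and fkbp5 (14.7 and 56.4 CPM, 3.84-fold, 2.59 to 5.75). Globin transcripts, which these cells should lack, were higher (median 0.999, 8 of 8 higher). The keratin, collagen, phototransduction and crystallin lists also lay outside the random range in this class. Thinning brought the collagen list inside it, keeping doublets the phototransduction list, and resolution 0.8 the crystallin list.

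In neuron-like cells the transcription factor genes otpa (32.3 and 5.87 CPM, 5.51-fold, 2.70 to 13.1), tfap2e (59.6 and 13.2 CPM, 4.51-fold, 2.78 to 7.77) and tfap2b (62.9 and 17.6 CPM, 3.57-fold, 2.33 to 5.70, doublets kept 2.07, thinned 2.37) were higher. The receptor genes rxraa (158 and 363 CPM, 2.29-fold, 2.03 to 2.60) and fgfrl1a (85.3 and 185 CPM, 2.17-fold, 1.82 to 2.58) and the chaperone gene fkbp5 (15.3 and 54.3 CPM, 3.56-fold, 2.46 to 5.19) were lower. Synaptic genes as a list did not differ (median 0.01, 16 of 32 higher). Immediate early genes were higher (median 0.32, 22 of 28 higher, inside the random range: 1000 UMIs, thinned). Mitochondrially encoded genes were lower (median -0.34, 12 of 13 lower, inside the random range: 10% mitochondrial limit, resolution 3, scaled by library), but not with a mitochondrial limit of 10% (0.01), at clustering resolution 3 (0.01) or with genes scaled within each library (0.12). Muscle transcripts appeared here as well: mylpfa (252 and 78.5 CPM, 3.21-fold, 2.62 to 3.96, doublets kept 1.82) and the sarcomere list (median 0.59, 22 of 25 higher, inside the random range: 10% mitochondrial limit, resolution 3, scaled by library), whose median was -0.01 with the mitochondrial limit of 10%.

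Both epidermal classes had more protein folding transcripts with PFOS. The heat shock and unfolded protein response list was higher in basal (median 0.30, 22 of 32 higher, thinned -0.11, inside the random range: 10% mitochondrial limit, thinned) and superficial (median 0.46, 29 of 35 higher, thinned -0.03, inside the random range: thinned) epidermis-like cells. In superficial cells herpud1 (107 and 33.9 CPM, 3.15-fold, 2.46 to 4.09), the cytokine gene tnfb (213 and 76.2 CPM, 2.79-fold, 2.36 to 3.31) and relb (94.1 and 35.2 CPM, 2.67-fold, 2.08 to 3.46) were higher. So were pmaip1 (211 and 88.8 CPM, 2.38-fold, 2.03 to 2.80), sqstm1 (1176 and 738 CPM, 1.59-fold, 1.503 to 1.69) and the list of Nrf2 targets (median 0.22, 22 of 29 higher). In basal cells hyou1 (102 and 29.5 CPM, 3.46-fold, 2.51 to 4.85) and the mitotic genes cenpe (33.8 and 7.52 CPM, 4.50-fold, 2.41 to 9.01) and aspm (37.1 and 11.6 CPM, 3.21-fold, 1.90 to 5.65) were higher. The cell cycle (median 0.60, 13 of 18 higher) and inflammation lists (median 0.38, 10 of 13 higher, inside the random range: thinned) were higher there as well. Hemoglobin, neural progenitor and phototransduction lists, which mark other cells, also lay outside the random range in basal cells. Each came inside it at 1000 UMIs. Hemoglobins also did at the 10% mitochondrial limit and resolution 3, and progenitor genes after thinning and with the doubled gene filter. Lower genes were klf9 (9.94 and 34.7 CPM, 3.49-fold, 1.96 to 6.62), klf2a (11.3 and 31.8 CPM, 2.82-fold, 1.61 to 5.19) and foxo3b (92.8 and 197 CPM, 2.13-fold, 1.74 to 2.61) in basal cells. In superficial cells the lower genes were fkbp5 (47.6 and 173 CPM, 3.62-fold, 2.97 to 4.45), klf2a (9.96 and 34.3 CPM, 3.45-fold, 2.21 to 5.54), slco2a1 (68.6 and 209.8 CPM, 3.06-fold, 2.58 to 3.64) and rorab (48.7 and 139 CPM, 2.85-fold, 2.32 to 3.51). The 2-fold genes of basal cells were 55.0% higher by total scaling and 44.4% by median ratio scaling.

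Collagen and matrix genes were lower with PFOS in fibroblast-like cells (median -0.33, 28 of 36 lower) and higher in fin fold mesenchyme-like cells (median 0.36, 22 of 30 higher, inside the random range: doublets kept, thinned). In cartilage-like cells they went both ways (median -0.25, 13 of 24 lower, inside the random range: halved gene filter). Cartilage-like cells had less ecrg4a (28.8 and 261 CPM, 9.07-fold, 5.80 to 14.9, doublets kept 4.15), nog3 (59.05 and 279 CPM, 4.73-fold, 3.42 to 6.69, doublets kept 2.70) and acanb (28.8 and 89.97 CPM, 3.12-fold, 1.92 to 5.298, doublets kept 1.98). They also had less large2 (102 and 255 CPM, 2.51-fold, 1.93 to 3.30) and pcna (63.2 and 182 CPM, 2.88-fold, 2.07 to 4.08, without richest cell 4.38). They had more angptl2b (71.4 and 10.6 CPM, 6.75-fold, 3.39 to 14.9, doublets kept 3.98) and notch3 (52.2 and 12.7 CPM, 4.11-fold, 2.102 to 8.64, without richest cell 6.30). Keratin genes, which mark epithelia such as skin and gut, were higher in the cartilage class (median 1.07, 15 of 18 higher). Its 2-fold genes were 73.0% higher by total scaling and 62.2% by median ratio scaling, which shifted all its genes by -0.10 log2. In fibroblast-like cells tnmd (30.02 and 82.7 CPM, 2.75-fold, 2.09 to 3.67), sost (29.6 and 81.8 CPM, 2.76-fold, 2.09 to 3.69) and lum (82.9 and 164 CPM, 1.97-fold, 1.66 to 2.36) were lower. The matrix genes postna (13.1 and 31.1 CPM, 2.37-fold, 1.54 to 3.74) and hyal4 (17.3 and 50.7 CPM, 2.92-fold, 2.04 to 4.28) were lower as well. The genes rrad (74.4 and 14.1 CPM, 5.29-fold, 3.63 to 7.93, thinned 2.18), timp2b (179 and 60.9 CPM, 2.94-fold, 2.43 to 3.58, thinned 1.88) and grem2b (98.1 and 36.2 CPM, 2.71-fold, 2.104 to 3.52) were higher. In fin fold mesenchyme-like cells ribosomal protein genes were higher (median 0.38, 71 of 72 higher). At equal cluster shares that median was 0.18. Cluster 35 of the class held 18 DMSO and 38 PFOS cells, with 21.8% ribosomal protein UMIs against 9.01% in cluster 15. The matrix gene fn1b (177 and 36.96 CPM, 4.79-fold, 3.54 to 6.61) and the regulator twist1a (308 and 76.8 CPM, 4.01-fold, 3.24 to 5.01, doublets kept 1.65, thinned 2.52, without richest cell 6.92, equal clusters 2.02) were higher too. The genes hce2l2 (15.103 and 78.3 CPM, 5.18-fold, 3.25 to 8.61) and tspearb (30.2 and 81.9 CPM, 2.71-fold, 1.90 to 3.93, thinned 1.78) were lower there. Hemoglobin and neural progenitor lists, which mark other cells, also lay outside the random range in fin fold cells. In fibroblast-like cells intestinal absorption, sarcomere, synaptic and phototransduction lists did. Sarcomere genes came inside it with the doubled gene filter and synaptic genes at 1000 UMIs. Phototransduction genes did at 1000 UMIs, with doublets kept and with the halved gene filter.

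Summed over the class, erythroid-like cells had slightly more globin and less of most other transcripts with PFOS. The median depth of the class was 9805 UMIs with PFOS and 3574 with DMSO. Globin and heme genes (median 0.15, 13 of 19 higher, thinned -0.01, inside the random range: thinned) included hbbe3 (6257 and 3092 CPM, 2.02-fold, 1.96 to 2.09). Glycolysis genes were lower (median -1.05, 7 of 7 lower, inside the random range: halved gene filter). At equal cluster shares the globin and heme median was 0.08 and the glycolysis median -0.67. Lower genes included igfbp1a (22.1 and 159.7 CPM, 7.23-fold, 5.14 to 10.4, thinned 4.73) and znrf3 (9.56 and 78.4 CPM, 8.21-fold, 4.90 to 14.7, doublets kept 4.71, equal clusters 5.34). The transporter spns2 (448 and 1362 CPM, 3.04-fold, 2.80 to 3.30) and the kinase gene wnk4b (249.7 and 764 CPM, 3.06-fold, 2.75 to 3.42, thinned 1.94, equal clusters 1.92) were lower too. The median of all genes in the class was -0.36 log2, and median ratio scaling shifted it by 0.28. The higher share of its 2-fold genes was 5.41%, and 22.8% with that scaling.

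Some genes had ratios in the same direction across most cell classes. Of 6279 genes measured in at least 5 classes, 70 had a median over classes at least 1.5-fold higher and 51 at least 1.5-fold lower, and 9 and 5 passed 2-fold. The glucocorticoid-induced gene fkbp5 was lower in all 9 classes where it was measured (median -0.94, -1.94 to -0.67), and thrab in all 11 (median -0.68, -1.42 to -0.08). Muscle transcripts were higher in most classes. For mylpfa this held in all 11 classes (median 1.53, 0.04 to 2.45), for the myhz1.1 locus ENSDARG00000067990 in 6 of 6 (median 1.72, 0.03 to 3.04), for mylz3 in 6 of 6 (median 1.298, 0.51 to 1.45) and for myhz2 in 4 of 5 (median 1.35, -0.41 to 2.01). A second locus with the symbol myhz1.1, ENSDARG00000102414, was lower over all cells (log2 ratio -0.77). The sarcomere list had a median above 0 in 8 of 10 classes. The lysozyme gene lyz was higher in 7 of 7 (median 1.55, 0.90 to 1.96) and timp2b in 7 of 7 (median 1.35, 0.15 to 2.67). The Notch targets her4.1, in 8 of 9 (median 1.26, -1.07 to 1.79, 0.58 to 1.27 over settings), and her2, in 6 of 7 (median 1.31, -0.22 to 3.45, 0.29 to 1.38 over settings), were also higher. Also lower across classes were the trypsin gene prss59.2 in 5 of 5 (median -2.74, -9.30 to -1.75), opn1sw1 in 8 of 10 (median -1.36, -2.15 to 2.504), fabp2 in 8 of 8 (median -1.07, -1.49 to -0.39) and krt92 in 8 of 9 (median -1.05, -2.03 to 0.07). The gene paqr6 was lower in 5 of 5 (median -0.83, -1.33 to -0.42). For many of these genes another class had over 10 times the CPM, and free RNA was not separated from transcripts of the class itself. Such a gap was found for mylpfa in 11 classes, myhz1.1 in 6, mylz3 in 6, myhz2 in 5, lyz in 7, timp2b in 1, her4.1 in 8 and her2 in 6. It was found for prss59.2 in 5, opn1sw1 in 9, fabp2 in 7 and krt92 in 7, for paqr6 in 0, and for fkbp5 and thrab in 0 and 0.

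**Figure D3:**
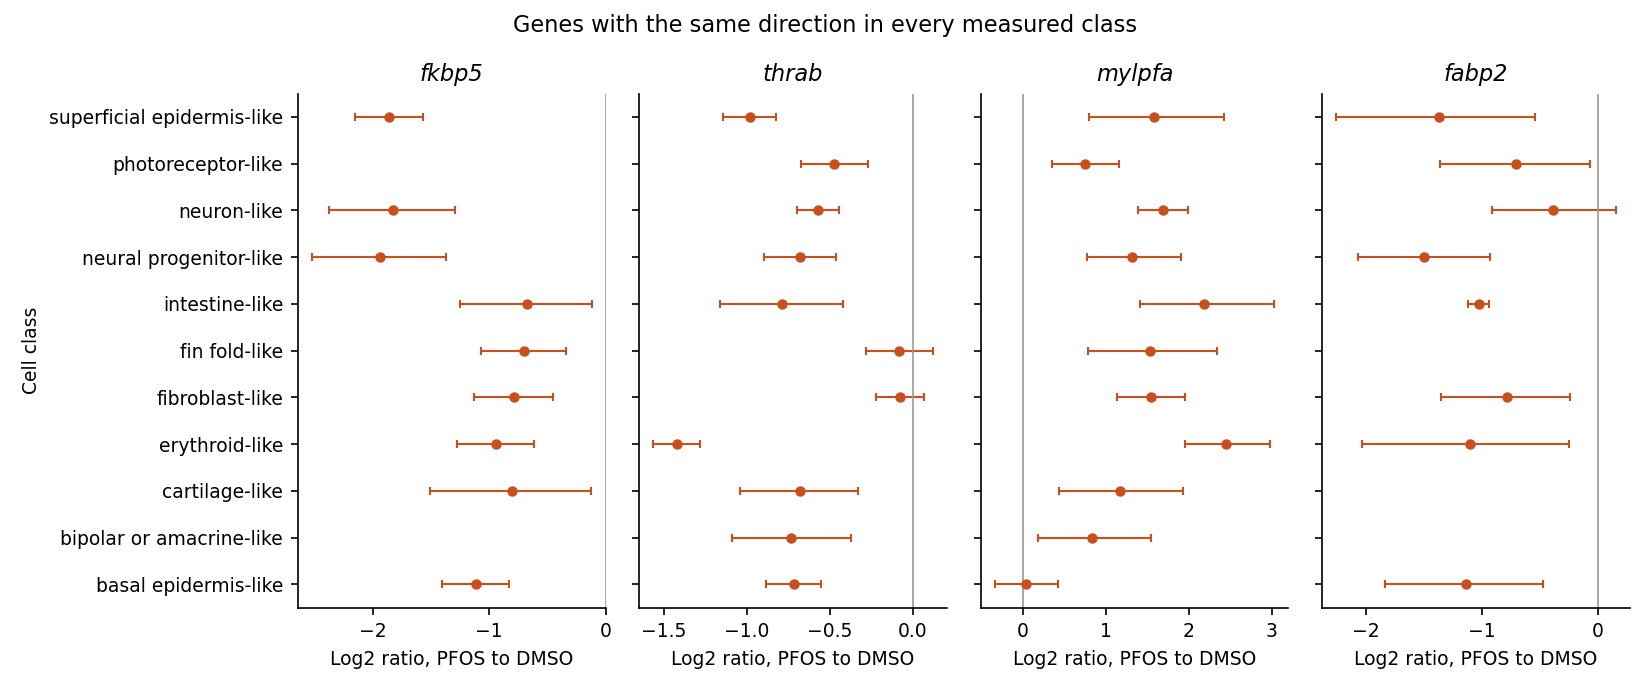
Log2 ratio of PFOS to DMSO for fkbp5, thrab, mylpfa and fabp2 in each class with at least 100 cells per library and at least 50 UMIs of the gene, with exact 95% intervals that cover counting error only.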

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

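The 3 differences below were picked after the results were seen, and none of them was tested. Each is a gene list whose median lay outside the central 95% of random lists on opposite sides in 2 classes, with at least 8 measured genes and with doublets kept as well. Those limits were also set after the data were seen.

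Keratin genes were higher with PFOS in cartilage-like cells (median 1.07) and lower in erythroid-like cells (median -0.75), a difference of 1.815 that was not tested. The erythroid list fell inside the random range after thinning and with the doubled gene filter. Hemoglobin and heme synthesis genes were higher in neural progenitor-like cells (median 0.999) and lower in intestinal epithelium-like cells (median -0.56), a difference of 1.562 that was not tested. The intestinal list fell inside the random range among cells of at least 1000 UMIs and 500 genes. Keratins are proteins of skin and other epithelia, and krt92 was abundant in intestinal epithelium-like cells (1530 CPM with PFOS and 1454 with DMSO). Hemoglobins are red blood cell proteins. Transcripts from other cells were not separated from those of each class. Nuclear oxidative phosphorylation genes were higher in basal epidermis-like cells (median 0.23) and lower in intestinal epithelium-like cells (median -0.62), a difference of 0.851 that was not tested. The basal list fell inside the random range among cells of at least 1000 UMIs and 500 genes and after thinning.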

How the results depend on the processing

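The values without the richest cell, with equal cluster shares and with clusters named without the added limit come from tests chosen only after the results were seen. No paired analysis or count of other splits applies, with 1 library per treatment.

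Shares of the 19 classes were compared over 6 planned settings of filters and clustering, or 5 for smooth muscle-like cells, and no planned setting turned a direction outside its counting interval. With clusters named without the added limit, the log2 share ratio of skeletal muscle-like cells was -0.0719 rather than 1.02, because a cluster of mixed lens and muscle transcripts joined the class. With a mitochondrial limit of 10%, 2 classes instead of 4 were at least 1.5-fold higher; the cause was not tested. In neurons that limit gave medians of 0.0077 for mitochondrially encoded and -0.0091 for sarcomere genes. The mitochondrial median there was also 0.0128 at resolution 3 and 0.12 with genes scaled within each library. The cause was not tested.

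Thinning to 1000 UMIs leaves fewer UMIs, so fewer genes passed the filter. Whole-library genes at least 2-fold apart were then 162 higher and 98 lower, and gene and class pairs 239 and 313. Genes with a median over classes at least 1.5-fold apart were 11 higher and 10 lower. Pairs of list and class outside the central 95% of random lists were 10 above and 9 below. Thinning also turned the medians of ion transport genes over all cells (0.0595) and of fatty acid oxidation genes in intestinal cells (0.30). The same held for heat shock and unfolded protein genes in basal (-0.11) and superficial epidermis (-0.0315) and for hemoglobin genes in erythroid cells (-0.0127). The cause of these turns was not tested.

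A gene filter of 0.5 times the minimum admits more genes by its construction, and one of 2 times fewer. Pairs at least 2-fold higher were 4899 and 745, and lower 4104 and 850. Genes with a median over classes at least 1.5-fold higher were 209 and 28, and lower 135 and 25. With the doubled filter, 222 genes were at least 2-fold higher in the whole library.

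At equal class shares, 105 whole-library genes were at least 2-fold higher. The log2 ratios of fabp7a (-0.0854), syt1a (-0.12) and hbbe1.3 (0.76) changed sign. That setting removes differences in class shares by construction. Without the richest cell the log2 ratio of sst1.1 was -0.11.

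Median ratio scaling and totals without mitochondrial and ribosomal protein genes moved no total of genes, of pairs or of lists by over 1.5 times. Matching in 10 bins bears only on the lists and moved none of their totals by that much. Median ratio scaling turned no named gene or list. Totals without mitochondrial and ribosomal protein genes turned no list and no gene compared across classes. They were not run on the genes named in single contexts. In 2 single classes median ratio scaling moved more: the 2-fold genes of erythroid cells went from 17 to 37 higher and 297 to 125 lower, and those of bipolar or amacrine cells from 163 to 309 and 209 to 124. Of 587 alternative values for 131 genes named with values in single contexts, 177 moved without a change of sign and 4 changed sign. For gene list medians, 72 of 659 values moved, and a further 9, of lists outside the random range, changed sign. The bipolar or amacrine class fell below 100 DMSO cells with doublets kept (98) and after thinning (88), and the cartilage class below 100 PFOS cells after thinning (97), so these settings gave no value there. Of the 110 most extreme pairs within classes, 51 had over 50% of their UMIs in 1 cell.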

Other observations

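The tests on clusters by ribosomal protein transcripts, on deeper cells, on cell cycle genes, on muscle genes by class, on the cells richest in muscle transcripts and on median ratio scaling were chosen only after the results were seen. The test on the cells richest in muscle transcripts replaced an earlier one, set before the result, whose upper bound lay above the value for all cells. The test on muscle genes by class replaced a count of classes that restated the pattern, and the lower bound for erythroid and intestinal cells was reset after their values were seen. The values for small classes were also chosen after they were seen, and other lists outside the random range there are not all given.

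Classes too small for the report were compared with doublets kept, at 10 or more cells in each library. Macrophage-like cells (66 DMSO and 85 PFOS cells) had a higher inflammation list with PFOS (median 0.76, 11 of 13 higher). Their collagen and matrix list was higher still (median 1.39, 6 of 9 higher), and their keratin list had a median of 0.24, so transcripts of other cells were not excluded. The cytokine gene tnfb was 3.98-fold (3.09 to 5.2005) higher, il6 4.32-fold (2.09 to 10.04), the tissue factor gene f3b 3.48-fold (2.60 to 4.74) and cxcl8a 1.86-fold (1.62 to 2.14). Without the richest cell the log2 ratio of cxcl8a was 1.62 rather than 0.90. Neutrophil-like cells had more lyz (2.49-fold, 2.41 to 2.57), whereas their inflammation list was lower (median -0.32). Hepatocyte-like cells (55 and 46 cells) had lower apolipoprotein (median -1.13, 10 of 10 lower) and complement genes (median -0.46, 22 of 29 lower). Their keratin genes were lower too (median -0.53, 10 of 11 lower), and 45.6% of PFOS against 21.8% of DMSO cells of the class scored as doublets.

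Lens-like cells (40 and 37 cells) had lower crystallin transcripts (median -2.11, 30 of 30 lower), while mitochondrially encoded genes were higher (median 1.27, 9 of 9 higher). Exocrine pancreas-like cells (16 and 20 cells) had lower digestive enzyme transcripts (median -3.05, 21 of 21 lower). Their keratin median was 5.07 and their median depth 38137 UMIs with PFOS against 9390 with DMSO. Transcripts of other epithelial cells were therefore not excluded in the PFOS cells of this class. Smooth muscle-like cells had lower glycolysis genes (median -1.55, 14 of 14 lower). In the same cells collagens were lower (median -0.56), keratins (0.33) and hemoglobins (0.40) higher, and the median depth was 2825 UMIs with PFOS against 5686 with DMSO. Ionocyte-like cells had higher Nrf2 targets (median 0.44, 17 of 23 higher), but their collagen (median -1.98, 7 of 7 lower) and inflammation lists (median -1.95, 5 of 5 lower) moved further, downward. Olfactory sensory neuron-like cells had less fkbp5 (4.44-fold, 2.27 to 9.48). Their collagen (median -1.51, 8 of 8 lower) and keratin lists (median -0.95, 16 of 17 lower) were lower too, and 31.8% of PFOS against 8.82% of DMSO cells scored as doublets. For ionocyte-like cells these percentages were 36.7 and 10.3.

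The PFOS library held more neurons and fewer erythroid cells. For the neurons, nucleus-like barcodes, poor in ribosomal protein transcripts, are argued against as the whole cause. The neuron cluster richest in these transcripts (33 DMSO and 139 PFOS cells) had 3.302 times the DMSO share. Barcodes of few UMIs are argued against as the whole cause of the neuron ratio too. It was 2.237 among cells of at least 1000 UMIs and 500 genes. Both tests used neuron shares only. The erythroid ratio was between 0.388 and 0.444 over the 6 other settings of filters and clustering, which include that limit. Nucleus-like barcodes in cluster 3, which held most neurons and 3.26% ribosomal protein UMIs, cannot be told apart: its share was 2.505 times the DMSO share, while the 2 poorest other clusters had 0.815 and 0.867, between the bounds set. An earlier developmental stage of the PFOS larvae cannot be told apart either, as the cell cycle list had a median above 0 in 8 of 11 classes (-0.43 to 0.64), between the bounds set, and unequal survival in dissociation and the clutch stay open.

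Muscle transcripts were higher with PFOS in most other classes. Doublets or fragments in a few cells of most classes are argued against for the summed sarcomere list only. Without the 5% of cells richest in these genes, 9 of 11 classes kept at least 50% of their difference in that list. The median over classes was 0.37 against 0.396 with all cells. In basal epidermis-like cells the difference rose from 0.267 to 0.666. Single genes with larger ratios, such as mylpfa (median 1.53), were not tested in this way. In the other 2 classes doublets or fragments cannot be told apart, as erythroid cells kept 24.1% and intestinal cells 39%. Free RNA from broken muscle cannot be told apart either: muscle genes at least 10 times more abundant in another class had a median of 0.472 log2 over 11 classes (0.04 to 1.23), against 0.852 in the rest of the library, between the bounds set. A change in muscle itself stays open: with doublets kept, skeletal muscle-like cells had higher sarcomere (median 0.49, 26 of 37 higher) and muscle energy genes (median 0.59, 16 of 23 higher), but also higher keratins (median 0.43).

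The gene fkbp5 was lower in every class where it was measured. Scaling by total UMIs is argued against, since the median over classes was -0.905 with median ratio scaling. Weaker glucocorticoid receptor signalling may be involved, but other glucocorticoid-induced genes had a median below 0 in only 7 of 11 classes (-0.54 to 0.45), which lies between the bounds set. Collection at another time of day also cannot be told apart. The period, cryptochrome and Rev-erb genes minus the Bmal and Clock genes differed by -0.378 log2 in the whole library, again between the bounds set. There 13 of 15 genes of the first arm (median -0.29) and 3 of 7 of the second (median 0.09) were lower. In neurons 12 of 12 and 6 of 7 were lower, in photoreceptors 11 of 11 and 4 of 6. In cartilage 0 of 4 measured genes of the first arm were lower.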
